A study of Mus musculus with 9 samples.

How the data were processed

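Liver RNA was sequenced from db/db mice, which lack a working leptin receptor and become obese and diabetic. Per the labels, the mice received PBS (vehicle), FGF19WT or FGF19ΔKLB for 12 weeks, and each group holds 3 libraries. Total RNA was extracted with TRIzol and its integrity was read on a Bioanalyzer. The labels name Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 without saying what each did, and they give the genome build as mm8. The positions in the deposited table do not follow that build: all 28517 gene identifiers, chromosomes and gene starts match GENCODE M21 on GRCm38, as do 25998 gene ends, while 2519 ends differ. Coordinates are therefore given on GRCm38. Group names follow the sample titles. The column headers use the code F19_HBS for the group titled FGF19ΔKLB, and the sample descriptions give that code beside those titles. The labels do not say what HBS stands for, so which change the protein of this group carries is not settled by them.

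The deposited table gives an expected count and an FPKM value per gene and library, both computed by the authors. The counts are whole numbers that the authors did not scale for library size. The ratio of count to FPKM was taken in 689 genes with a single transcript and a count of at least 500. Divided by the ratio of the same gene in vehicle library 1, it was constant within each library to 0.171%. Both units thus carry the same signal between libraries. Low counts piled up at multiples of 4, where genes were 3.28 to 3.65 times as frequent as at neighbouring counts, so 1 read pair gives about 4 counts. Count totals of 65.1 to 73.3 M per library thus stand for about 16.3 to 18.3 M read pairs. Of the genes listed, 16777 are protein coding, and 122 symbols occur more than 1 time, so genes were joined by identifier. How the authors chose which genes to list is not stated.

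The 3 comparisons were fitted with edgeR 4.0.16 in R 4.3.3 as 1 quasi-likelihood model over all 9 libraries, with TMM factors, a robust fit, group as the only term and 6 residual degrees of freedom. Genes with low counts were removed by the filter that edgeR offers, which left 18142 genes. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Intervals of log2 fold changes are 95% intervals from that fit. Levels are CPM values, counts scaled to the library total with TMM factors, as mean ± SD over 3 libraries. The same model was also fitted to the 6 libraries of the 2 groups compared, since a pooled error takes in the spread of the group left out. This and every setting below was fixed before the data were examined unless said otherwise.

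Of 42 gene lists written down in advance, 41 had at least 3 measured members and were tested, with 662 distinct genes among them. The list of pancreas genes had 1 of its 11 members past the filter and was not tested over 9 libraries. In all, 8 listed symbols were absent from the table and 1 was matched through a renamed symbol. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 41 lists, and again with an estimated correlation. The fry test, which asks whether a list moved one way on balance, was run beside it. Members past the test are counted over all genes and adjusted over the list alone. Cell type lists are read only as list tests, since the tissue was not sorted.

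Genes named in the text follow a rule. It takes 19 genes of bile acid, lipid and glucose metabolism, FGF signalling and growth, always. It adds up to 8 called genes per direction and comparison with a mean of at least 1 CPM and no overlap between groups, up to 4 members with the smallest p of each list past its test, and up to 3 called members of a list. Applying the rule also to calls of the 6-library fits was decided after the data were seen. A gene outside the rule, for the comparison at hand, is said to have been chosen after its values were seen, apart from genes that overlap a named gene and members listed to spell out a count.

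The procedure was tested on simulated data with the group sizes and spread of these libraries, in which 200 genes and 5 lists were shifted. Over 9 libraries it recovered 34.3% of genes shifted by 4-fold and 57.6% of those shifted by 8-fold for FGF19WT against vehicle. For FGF19ΔKLB against vehicle it recovered 40.3% and 63.6% over 9 libraries, and 67.2% and 77.3% over 6. Between 1 and 6 unchanged genes were called per fit, and 0 lists that were not shifted. Genes were drawn independently of each other, so the simulation cannot say how often lists of correlated genes pass without a shift.

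Alternatives were no filter, a filter of 5 CPM in at least 3 libraries, DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma on log2(FPKM + 1) for genes with at least 1 FPKM, the 6-library fits, the replicate number as a block, and leaving out each library in turn. Dividing counts by 4, leaving out FGF19WT libraries 2 and 3 together (with the filter applied anew or with the genes tested over 9 libraries), and the alternatives of the 6-library fit were added after the data were seen. The labels do not say whether equal replicate numbers share an animal, cage or day, so no block was used in the fits reported. The similarity of the responses was set beside 40 simulations in which neither treated group differed from vehicle but both shared the same 3 vehicle libraries. Its value under each other choice of libraries or filter was set beside 7 such simulations, which was added after the data were seen. All of these simulations drew genes independently of each other and left out genes with no counts in vehicle. They cannot say how far correlated genes would widen the simulated range. Summaries and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.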

Results

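FGF19 is a hormone of the intestine that acts on hepatocytes through the receptor FGFR4 and its co-receptor β-klotho, encoded by Klb, and lowers bile acid synthesis. FGF19ΔKLB is a variant of it whose sequence change the labels do not give. The column headers carry the code F19_HBS where the titles have FGF19ΔKLB, and the labels do not say what HBS stands for. The series asks whether a variant with less ability to pair FGF receptors carries less tumour risk. Liver RNA of db/db mice was profiled after 12 weeks of PBS vehicle, FGF19WT or FGF19ΔKLB. Each group held 3 libraries. Total counts were 73.3, 68.8 and 72.3 M for vehicle, 70.6, 69.8 and 65.1 M for FGF19WT, and 73.3, 69.1 and 72.0 M for FGF19ΔKLB. Albumin transcripts took 8.6% to 13.5% of the counts in vehicle, 8.7% to 16.4% with FGF19WT and 16.3% to 21.1% with FGF19ΔKLB. The labels do not say whether the replicates are separate animals, so each p-value measures the spread between these samples.

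FGF19WT libraries 2 and 3 stood apart from FGF19WT library 1 and from the other groups. The first principal component held 48.9% of the variance and placed them at 129.8 and 169.9. FGF19WT library 1 lay at −41 on it, the vehicle libraries between −64 and −60.4, and the FGF19ΔKLB libraries between −37.7 and −7.9. Both libraries lay above or below the other 7 in 6788 of 18142 genes, 37.4% where chance gives 5.6%. The next pair of libraries did so in 10.2%. All 16 Wnt and pericentral genes, which mark hepatocytes around the central vein, were above the other 7 libraries in both. All 12 periportal genes were below. Glutamine synthetase, Glul, on chromosome 1 from 153899944 to 153909723, stood at 14770.2 and 12685.4 CPM in FGF19WT libraries 2 and 3. It stood at 185 in FGF19WT library 1, at 549 to 1000 in vehicle and at 224 to 364 with FGF19ΔKLB. Glul was chosen after its values were seen. The Wnt feedback gene Nkd1 stood at 326 and 379 CPM in these libraries and between 1.75 and 4.42 in the other 7. The periportal Cyp2f2 stood at 7.39 and 4.83 CPM there, against 122 to 584 in the other 7. Of 35 cell cycle genes, 27 were above the other 7 libraries in both, as were 15 of 25 ribosomal protein genes and 11 of 17 genes of ERK feedback. Both were below the other 7 in 11 of 14 Kupffer cell markers, 10 of 12 sinusoidal endothelial markers and 8 of 9 B and plasma cell markers. The lower levels were not limited to these cell types. Both were also below the other 7 in 8 of 14 hepatocyte markers, 15 of 22 acute phase genes, 9 of 11 gluconeogenesis genes and 13 of 20 amino acid catabolism genes.

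**Figure D1:**
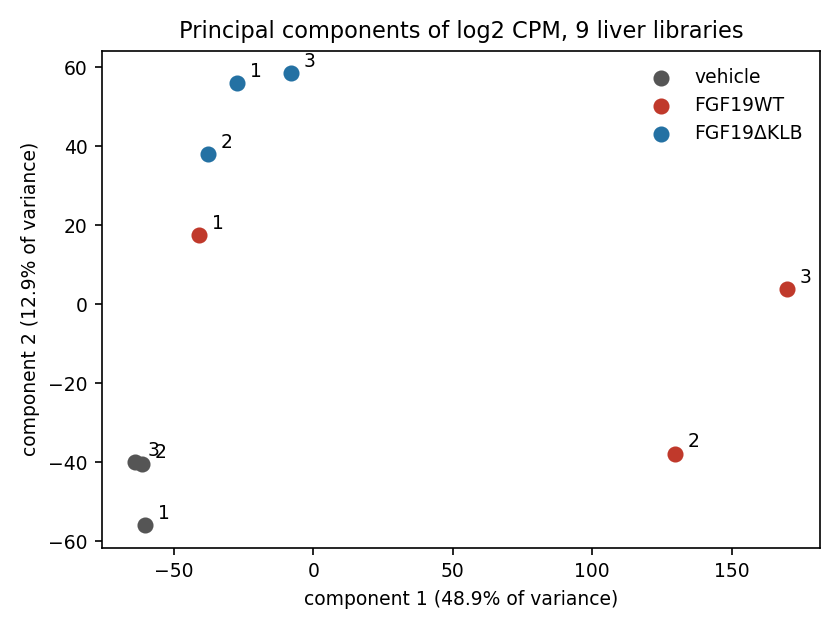
Each point is 1 library on the first (48.9% of the variance) and second (12.9%) principal component of log2 CPM, coloured by group, with 3 libraries per group. FGF19WT libraries 2 and 3 lie at 129.8 and 169.9 on the first component and the other 7 libraries between −64 and −7.9.

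The comparison of FGF19WT with vehicle asks what the natural hormone changed in the livers. Cidec, which fuses lipid droplets, fell from 29.8 ± 4.18 to 3.1 ± 1.51 CPM (SD, n = 3; log2 fold change −3.27, SE 0.41, adjusted p = 0.0471 in edgeR). Plin5, which coats lipid droplets, fell from 50.9 ± 8.32 to 19 ± 0.883 CPM (−1.42, SE 0.16, adjusted p = 0.0406). Clstn3, a calsyntenin with a form that sits on lipid droplets, fell from 27.1 ± 8.96 to 4.86 ± 1.15 CPM (−2.48, SE 0.29, adjusted p = 0.0406). Cidec and Plin5 were lower than vehicle in each of the 3 FGF19WT libraries, at 3.93, 4.01 and 1.35 CPM for Cidec and 18, 19.2 and 19.7 CPM for Plin5. Blnk, an adaptor of B cell receptor signalling, rose 16.4-fold from 1.21 ± 0.233 to 19.8 ± 9.42 CPM (adjusted p = 0.0406), with 9.03 CPM in FGF19WT library 1 and 24.2 and 26.3 in libraries 2 and 3. Card10, a scaffold of NF-κB signalling, rose 2.74-fold to 19.4 ± 0.658 CPM (adjusted p = 0.0406). Ttc38 rose 2.72-fold. Ephb2, a receptor for ephrins, fell from 11 ± 3.25 to 0.208 ± 0.132 CPM. Of the antibody genes 4 were called lower, Ighg1, Igkv8-24, Igkv10-94 and Igkv12-44, each in 1 of the 9 fits that leave out a library and not over the 6 libraries of these groups or with a replicate block. Igkv10-94 was chosen after its values were seen. Ighg1, a constant region of IgG, fell from 109 ± 48.2 to 0.761 ± 0.618 CPM (adjusted p = 0.0471). Igkv12-44 and Igkv8-24 had no counts in any FGF19WT library, which made them at least 29.8-fold and 15.9-fold lower than vehicle against a floor of 12 counts per library. The floor covers counting error only. On GRCm38, Cidec lies on chromosome 6 from 113424634 to 113435760 and Plin5 on chromosome 17 from 56111601 to 56117596. Clstn3 lies on chromosome 6 from 124430759 to 124464794, Blnk on chromosome 19 from 40928927 to 40994535 and Card10 on chromosome 15 from 78775138 to 78803042.

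Of 18142 genes tested by edgeR over 9 libraries, 5 rose and 15 fell with FGF19WT. An unadjusted p under 0.05 was reached by 3412, of which 2130 were higher and 1282 lower, and the groups did not overlap in 22.6% of genes, where chance gives 10%. DESeq2 called 1743 genes (1141 rose, 602 fell) and limma 69 (14 rose, 55 fell), among which were all 20 and 17 of these genes. The balance of directions thus differed between tools. The count rested on single libraries. It was 0 without vehicle 2, FGF19WT 3, FGF19ΔKLB 2 or FGF19ΔKLB 3, 1 without vehicle 1, FGF19WT 2 or FGF19ΔKLB 1, 3 without vehicle 3, and 5221 without FGF19WT 1. Cidec, Plin5 and Blnk were each called in 1 of the 9 fits that leave out a library and Clstn3 in 2. Over the 6 libraries of these groups the only call was Fam124a, a gene of unknown function, which fell from 11 ± 1.03 to 0.613 ± 0.0556 CPM (adjusted p = 0.0186). Of the 20 genes, 3 overlap another gene on the same strand.

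Among the preset lists, genes of growth signalling and of cell division stood higher with FGF19WT. Of 17 ERK pathway feedback and early genes, 15 had positive changes with a median log2 change of 1.72 (camera adjusted p = 8.06e-07, adjusted p = 0.593 with an estimated correlation). Of these 11 rose adjusted over the list alone and 0 over all genes. The transcription factor Etv5 stood at 7.97, 14.1 and 10.2 CPM against 1.7 to 3.39 in vehicle (adjusted p = 0.0752). The ERK phosphatases Dusp6 and Dusp4 were 3.28-fold and 8.52-fold higher (adjusted p = 0.0924 and 0.0841). Of 35 cell cycle genes, 34 had positive changes (median 3.25, adjusted p = 7.33e-12, adjusted p = 0.593 with an estimated correlation). Of these 25 rose adjusted over the list alone and 0 over all genes. The proliferation marker Mki67 stood at 2.92 CPM in FGF19WT library 1 and at 27.2 and 37.1 in libraries 2 and 3, against 0.704 to 1.48 in vehicle (adjusted p = 0.0986). The 25 ribosomal protein genes had a median change of 0.89 (adjusted p = 7.33e-12, adjusted p = 0.593 with an estimated correlation), of which 23 rose adjusted over the list alone and 0 over all genes. Rpl3 went from 158 ± 6.6 to 292 ± 6.03 CPM. Of 14 lipid droplet and PPARγ target genes, 11 had negative changes (median −0.86, adjusted p = 0.000504, adjusted p = 0.593 with an estimated correlation). Adjusted over the list alone 7 fell and 1 rose, and Plin5 and Cidec fell over all genes. Male-biased liver genes were lower (adjusted p = 0.00139, adjusted p = 0.593 with an estimated correlation), with 5 falling and 1 rising adjusted over the list alone. Genes of the unfolded protein and integrated stress response were higher (adjusted p = 0.0117, adjusted p = 0.593 with an estimated correlation), of which 5 rose adjusted over the list alone. This call was lost without vehicle 2 (0.0535), without FGF19WT 2 (0.128) and without both FGF19WT libraries 2 and 3 (0.961).

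Wnt and pericentral genes had a median log2 change of 3.30 with FGF19WT (adjusted p = 5.96e-05, adjusted p = 0.593 with an estimated correlation), and 14 of 16 rose adjusted over the list alone and 0 over all genes. The mean of the list stood 3.67 and 3.69 above vehicle in libraries 2 and 3 and −0.75 from it in library 1. With libraries 2 and 3 both left out the direction of this list turned (adjusted p = 0.00083, adjusted p = 0.66 with an estimated correlation and 0.313 by fry). In that fit the 1 FGF19WT library left is assumed to vary like those of the other groups. The 12 periportal genes were lower with a median of −1.22 (adjusted p = 0.000122, adjusted p = 0.593 with an estimated correlation), and their call was lost without both libraries (adjusted p = 0.266). Their list means were −5.4 and −4.88 in libraries 2 and 3 and 0.3 in library 1. The same pair carried the lower levels of acute phase genes (adjusted p = 0.000437), gluconeogenesis (0.000569) and amino acid catabolism (0.0148), each with adjusted p = 0.593 with an estimated correlation. Without both they were at 0.767, 0.474 and 0.106. Amino acid catabolism also lost its call without FGF19WT 2 alone (adjusted p = 0.105). Smaller falls were found for fatty acid oxidation (adjusted p = 0.0253, adjusted p = 0.645 with an estimated correlation) and the nuclear genes of the respiratory chain (adjusted p = 0.0148, adjusted p = 0.628 with an estimated correlation). Fatty acid oxidation lost its call without vehicle 1 (0.0649), vehicle 2 (0.152) or FGF19WT 1 (0.382), and the respiratory chain without FGF19WT 2 (0.188) or both (0.596). Of 41 lists, 21 passed camera, 5 higher and 16 lower, and none passed with an estimated correlation. Fry passed 3 lists, ERK feedback, lipid droplet genes and T and NK cell markers, each at an adjusted p of 0.0297. The 6 lists that kept their call in every fit leaving out 1 library and without both FGF19WT libraries 2 and 3 were ERK feedback, cell cycle, ribosomal proteins, lipid droplet genes, male-biased genes and T and NK cell markers.

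**Figure D2:**
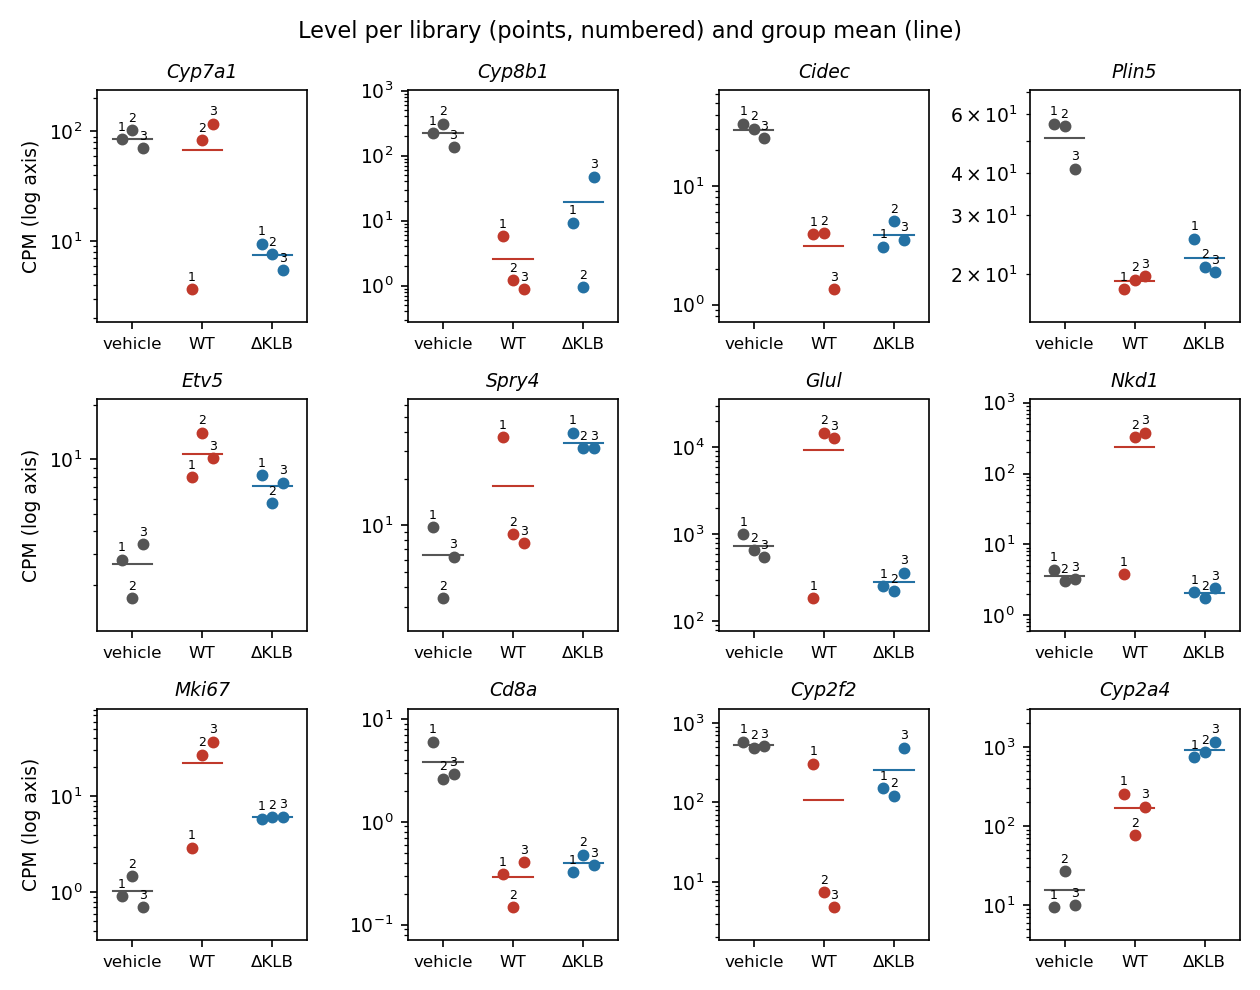
Level of 12 genes in each of the 9 libraries in CPM on a log axis, by group, where points are libraries and lines are group means. Cidec lies between 25.3 and 33.6 CPM in vehicle and between 1.35 and 5.02 in the 6 treated libraries, while Glul is at 14770.2 and 12685.4 in FGF19WT libraries 2 and 3.

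Markers of several cell types other than hepatocytes were lower with FGF19WT, while those of recruited macrophages (adjusted p = 0.126), cholangiocytes (0.474) and erythroid cells (0.845) did not pass. Of 12 T and NK cell markers, 11 had negative changes with a median of −1.69 (adjusted p = 0.000186, adjusted p = 0.593 with an estimated correlation), with 6 falling and 1 rising adjusted over the list alone and 0 over all genes. The CD8 chain gene Cd8a stood at 0.308, 0.148 and 0.406 CPM against 2.62 to 6.02 in vehicle (adjusted p = 0.0583). All 14 Kupffer cell and macrophage markers had negative changes (median −1.19, adjusted p = 4.65e-05, adjusted p = 0.593 with an estimated correlation). Their list mean was −0.24 in library 1 against −2.19 and −3.5 in libraries 2 and 3, and the call was lost without both (adjusted p = 0.152). B and plasma cell markers (adjusted p = 0.00215) and sinusoidal endothelial markers (0.00288), both with adjusted p = 0.593 with an estimated correlation, were likewise lowest in libraries 2 and 3. They lost their calls without both, at 0.965 and 0.0551. The immunoglobulin light chain Igkc stood at 9.54, 2.9 and 2.23 CPM against 79.8 to 189 in vehicle. Extracellular matrix and stellate cell genes (adjusted p = 0.00403) and neutrophil markers (0.0374) were lower, both with adjusted p = 0.628 with an estimated correlation. So were inflammatory genes (0.0108) and the 4 measured adipose tissue markers (0.0295), both with adjusted p = 0.593 with an estimated correlation, and 1 of the 4, Cidec, fell over all genes. Matrix genes were at 0.109 without FGF19WT 3, and without both FGF19WT libraries 2 and 3 matrix genes were at 0.535 and inflammatory genes at 0.265. Neutrophil markers lost their call without vehicle 2 (0.0993), vehicle 3 (0.177), FGF19WT 1 (0.0585), FGF19WT 2 (0.0911) or FGF19WT 3 (0.199), without both of the latter (0.817) and with a replicate block (0.0511). Adipose markers lost it without vehicle 1 (0.0734), FGF19WT 2 (0.162), FGF19WT 3 (0.227) or FGF19ΔKLB 1, 2 or 3 (0.0845, 0.0801 and 0.0857). In these fits 6 adipose markers were past the filter rather than 4, so library and list changed together. The losses cannot be put down to the library alone. Neutrophil markers likewise numbered 10 rather than 9 without vehicle 2, FGF19WT 1, FGF19WT 2 or FGF19WT 3. Without both FGF19WT libraries 2 and 3 the 4 adipose markers were at 0.647. When the low-count filter was applied anew to those 7 libraries, 9 adipose markers entered, so the list was another one and its higher value (5.45e-05, adjusted p = 0.203 with an estimated correlation) says nothing of these 4.

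The comparison of FGF19ΔKLB with vehicle asks which of these changes the variant also makes. Clstn3 fell from 27.1 ± 8.96 to 3.25 ± 0.455 CPM (SD, n = 3; log2 fold change −3.06, SE 0.30, adjusted p = 0.0462). Tlcd2, a gene of membrane lipid composition on chromosome 11 from 75461715 to 75470657, fell from 41.4 ± 4.27 to 14.9 ± 0.639 CPM (−1.47, SE 0.15, adjusted p = 0.0462). Tlcd2 overlaps Mir22hg, whose change was −0.57. These were the only calls by edgeR over 9 libraries. An unadjusted p under 0.05 was reached by 1515 genes, and the groups did not overlap in 24.6% of genes, where chance gives 10%. DESeq2 called 370 (182 rose, 188 fell) and limma 51 (10 rose, 41 fell). The count was 0 without vehicle 1, vehicle 2, FGF19WT 2 or any of FGF19ΔKLB 1, 2 and 3, 3 without vehicle 3, 5 without FGF19WT 3 and 172 without FGF19WT 1.

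Over the 6 libraries of vehicle and FGF19ΔKLB, which leave the spread of the FGF19WT libraries out of the error, edgeR called 292 of 17340 genes, of which 155 rose and 137 fell. On these libraries DESeq2 called 1378 (664 rose, 714 fell) and limma 469 (130 rose, 339 fell), so the balance of directions depended on the tool. The biological coefficient of variation was 0.326 there and 0.471 over 9 libraries. Without 1 library the count was 44 (vehicle 1), 95 (vehicle 2), 84 (vehicle 3), 70 (FGF19ΔKLB 1), 276 (FGF19ΔKLB 2) and 98 (FGF19ΔKLB 3). Of 14 bile acid synthesis genes tested in this fit, 3 fell over all genes, and 9 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.000169, adjusted p = 0.197 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of that pathway, on chromosome 4 from 6265612 to 6275633, fell from 86 ± 16.6 to 7.52 ± 2.01 CPM (−3.52, SE 0.25, adjusted p = 0.00606). Cyp7b1 and Cyp27a1 of the alternative pathway fell by 1.31 and 1.25 on the log2 scale (adjusted p = 0.0147 and 0.028). Over 9 libraries Cyp7a1 had the same change with an SE of 0.96 (adjusted p = 0.358). Of 14 lipid droplet genes 7 fell over all genes, and 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.15e-07, adjusted p = 0.197 with an estimated correlation). Cidec fell to 3.87 ± 1.02 CPM (−2.95, SE 0.22, adjusted p = 0.00606) and Plin5 to 22.2 ± 2.88 CPM (adjusted p = 0.0219). Mogat1, an enzyme of triglyceride synthesis, fell from 6.3 ± 1.32 to 0.624 ± 0.198 CPM (adjusted p = 0.00868). Mki67 rose from 1.03 ± 0.402 to 6.02 ± 0.137 CPM (2.54, SE 0.31, adjusted p = 0.018). Dusp6 rose from 21.5 ± 3.04 to 44.5 ± 5.4 CPM (adjusted p = 0.0246). Spry4, an inhibitor of the ERK pathway, rose from 6.47 ± 3.16 to 34.1 ± 4.73 CPM (adjusted p = 0.0385), and the early gene Egr1 from 13.9 ± 1.74 to 56.2 ± 23.3 CPM (adjusted p = 0.0465). Ephb2 fell by 5.49 on the log2 scale (adjusted p = 0.00606) and Blnk rose 5.15-fold (adjusted p = 0.0123). In the 6 fits that leave out a library, Clstn3, Tlcd2, Cyp7a1, Cidec, Mogat1 and Ephb2 were called in all 6. Blnk was called in 5, Cyp7b1 and Mki67 in 4, Plin5, Dusp6 and Spry4 in 2, and Cyp27a1 and Egr1 in 1. Of these genes limma did not call Ephb2, Blnk and Mki67. Mogat1 and Blnk were chosen for this comparison after their values were seen. Of the 292 genes, 39 overlap a gene on the same strand, and 4 of those overlap a gene that moved the other way.

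Of the preset lists over 9 libraries, 22 passed camera with FGF19ΔKLB, 10 higher and 12 lower. The 15 bile acid synthesis genes were lower with a median log2 change of −0.58 (adjusted p = 0.00272, adjusted p = 0.208 with an estimated correlation). In that list 6 fell and 2 rose adjusted over the list alone and 0 changed over all genes. Lipid droplet and PPARγ target genes were lower (median −0.99, adjusted p = 2.77e-09, adjusted p = 0.208 with an estimated correlation), with 8 falling adjusted over the list alone, and 7 over all genes in the 6-library fit. ERK feedback genes were higher in 16 of 17 members (median 0.79, adjusted p = 6.63e-07, adjusted p = 0.289 with an estimated correlation), with 7 rising adjusted over the list alone. The 25 ribosomal protein genes were higher with a median of 0.63 (adjusted p = 3.31e-13, adjusted p = 0.352 with an estimated correlation), with 12 rising adjusted over the list alone. T and NK cell markers were lower in 11 of 12 members (median −1.51, adjusted p = 3.14e-07, adjusted p = 0.208 with an estimated correlation), with 5 falling adjusted over the list alone. Cd8a fell in the 6-library fit from 3.85 ± 1.89 to 0.393 ± 0.0791 CPM (adjusted p = 0.0187), a call made in 3 of the 6 fits that leave out a library and not by limma. Fry passed bile acid synthesis (0.00258), lipid droplet genes (0.0122) and T and NK cell markers (0.0336).

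Genes that make fatty acids and cholesterol stood higher with FGF19ΔKLB. Of 22 lipogenesis genes, 18 had positive changes (median 0.37, adjusted p = 1.77e-05, adjusted p = 0.394 with an estimated correlation), with 4 rising adjusted over the list alone and 0 over all genes. Fatty acid synthase, Fasn, stood at 540, 528 and 606 CPM against 84, 379 and 200 in vehicle (adjusted p = 0.482), and its regulator Srebf1 at 227 ± 65.8 against 92.1 ± 37.1 CPM (adjusted p = 0.539). The 24 cholesterol synthesis and uptake genes were higher (median 0.60, adjusted p = 4.74e-05, adjusted p = 0.606 with an estimated correlation), with 4 rising adjusted over the list alone. This call was lost without FGF19ΔKLB 3 (adjusted p = 0.0592). Female-biased liver genes were higher in 16 of 17 members (median 2.23, adjusted p = 1.15e-06, adjusted p = 0.32 with an estimated correlation). Male-biased genes were lower (median −0.68, adjusted p = 0.00014, adjusted p = 0.351 with an estimated correlation), with 4 members of each list changing adjusted over the list alone. Cyp2a4, a steroid hydroxylase higher in female liver, stood at 924 ± 222 CPM against 15.6 ± 10.1 in vehicle and rose in the 6-library fit (5.89, SE 0.55, adjusted p = 0.0127) and in all 6 fits that leave out a library. All 13 transcripts of the mitochondrial genome were lower (median −0.36, adjusted p = 4.74e-05, adjusted p = 0.509 with an estimated correlation), of which 1 fell adjusted over the list alone.

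Further lists passed with FGF19ΔKLB. Interferon response genes were higher in 22 of 23 members (adjusted p = 0.000349, adjusted p = 0.551 with an estimated correlation), as were genes of the unfolded protein and integrated stress response (0.000349, adjusted p = 0.394 with an estimated correlation) and hepatocyte markers (0.00252, adjusted p = 0.515 with an estimated correlation). Cell cycle genes were higher in 32 of 35 members (median 0.70, adjusted p = 0.0013, adjusted p = 0.747 with an estimated correlation), with 0 rising adjusted over the list alone. This call was lost without FGF19ΔKLB 2 (adjusted p = 0.0508). The list means were −0.06, 1.15 and 1.28 in FGF19ΔKLB 1, 2 and 3. Liver tumour and oncofetal genes were higher (median 1.46, adjusted p = 0.0108, adjusted p = 0.289 with an estimated correlation), a call lost without vehicle 1 (0.057) or FGF19ΔKLB 3 (0.087). Without vehicle 1 the list held 16 members rather than 14, so that loss cannot be put down to the library alone. The fetal transcript H19 stood at 7.06 ± 3.94 CPM against 1.32 ± 0.107 in vehicle and rose in the 6-library fit (adjusted p = 0.0464), a call made in 1 of the 6 fits that leave out a library and not by limma. Fatty acid oxidation genes were lower (adjusted p = 0.00123, adjusted p = 0.663 with an estimated correlation), a call lost without vehicle 2 (0.0709) or FGF19ΔKLB 2 (0.0517). Wnt and pericentral genes were lower in 13 of 16 members (median −0.98, adjusted p = 0.0234, adjusted p = 0.75 with an estimated correlation), a call lost without vehicle 1 (0.0936), vehicle 2 (0.0695) or FGF19ΔKLB 2 (0.054). Inflammatory genes (0.00123) and the 4 adipose tissue markers (0.00104) were lower, each with adjusted p = 0.32 with an estimated correlation. B and plasma cell markers were lower (0.0354, adjusted p = 0.72 with an estimated correlation), a call lost without vehicle 1 (0.111), FGF19ΔKLB 1 (0.0507) or FGF19ΔKLB 3 (0.0806). Sinusoidal endothelial markers (0.0393) and matrix and stellate cell genes (0.0471), each with adjusted p = 0.75 with an estimated correlation, were lower. The endothelial markers lost their call without vehicle 1 (0.0865), vehicle 2 (0.0911) or FGF19ΔKLB 3 (0.199). The matrix genes lost it without vehicle 1 (0.0936), vehicle 2 (0.0572), vehicle 3 (0.0881), FGF19WT 2 (0.0579), FGF19ΔKLB 1 (0.556) or FGF19ΔKLB 3 (0.109), and with DESeq2 size factors (0.0588).

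The receptor genes and the enzymes that FGF19 is known for were read in both treated groups. Fgfr4 stood at 36.6 ± 0.223 CPM in vehicle, 33.5 ± 0.67 with FGF19WT and 42.1 ± 8.84 with FGF19ΔKLB (adjusted p = 0.675 and 0.818 against vehicle). Klb stood at 24.5 ± 4.7, 16.1 ± 9.78 and 27.1 ± 7.05 CPM in that order (adjusted p = 0.425 and 0.961), with 27.4 CPM in FGF19WT library 1 and 11 and 10 in libraries 2 and 3. Nr0b2, a repressor of Cyp7a1, stood at 29.1 ± 16, 36.9 ± 10.9 and 35 ± 4.52 CPM (adjusted p = 0.679 and 0.929). Cyp7a1 stood at 3.66 CPM in FGF19WT library 1 and at 83.4 and 118 in libraries 2 and 3, against 70.1 to 103 in vehicle. The FGF19WT group did not pass the test (log2 fold change −0.33, SE 0.87, adjusted p = 0.857). Cyp8b1, which makes cholic acid, on chromosome 9 from 121914356 to 121916305, stood at 5.71, 1.21 and 0.885 CPM with FGF19WT against 219, 311 and 136 in vehicle (−6.42, SE 1.44, adjusted p = 0.125). It stood at 9.34, 0.957 and 47.6 CPM with FGF19ΔKLB (adjusted p = 0.502). The bile acid synthesis list did not pass with FGF19WT (adjusted p = 0.526), with 3 members rising and 3 falling adjusted over the list alone. The mean of this list was −0.78, −0.62 and −0.65 from vehicle in FGF19WT libraries 1, 2 and 3, against −0.06 to 0.11 in the vehicle libraries. The list means of all 3 FGF19WT libraries were thus lower by a similar amount, but not through the same genes. Cyp7a1 was below vehicle in library 1 only, while Cyp8b1 was below it in all 3. In libraries 2 and 3 together, 3 of the 15 members lay above the other 7 libraries and 3 below, where chance gives 2.8 each way. The list was also lower with FGF19WT libraries 2 and 3 left out. Afp, a marker of fetal liver and liver tumours, stood at 6.67, 195 and 407 CPM with FGF19WT, at 1.9 to 2.78 in vehicle and at 3.96 to 14.5 with FGF19ΔKLB (adjusted p = 0.124 and 0.746). The tumour and oncofetal list did not pass with FGF19WT (adjusted p = 0.157). Its list means were 0.76, 2.11 and 1.95 above vehicle in FGF19WT libraries 1, 2 and 3. They were 0.94, 0.76 and 2 in FGF19ΔKLB libraries 1, 2 and 3. The list did not pass in the direct contrast of these groups, so its pass with FGF19ΔKLB alone shows no difference between them. Ccnd1, a cyclin of the G1 phase, stood at 59.5 ± 45.7 CPM with FGF19WT, 31.1 ± 12.9 with FGF19ΔKLB and 19.5 ± 5.45 in vehicle (adjusted p = 0.199 and 0.832). Scd1 stood at 1390.9 ± 512 CPM with FGF19WT and 4277.5 ± 1784 with FGF19ΔKLB against 5001.6 ± 1873.5 in vehicle (adjusted p = 0.128 and 0.945). Of the genes of glucose output, Pck1 stood at 1992.6 CPM in FGF19WT library 1 and at 43.3 and 49.7 in libraries 2 and 3 (adjusted p = 0.499). G6pc stood at 67.6 ± 61.5 CPM against 215 ± 156 in vehicle (adjusted p = 0.291). Neither passed with FGF19ΔKLB (adjusted p = 0.966 and 0.753).

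**Figure D3:**
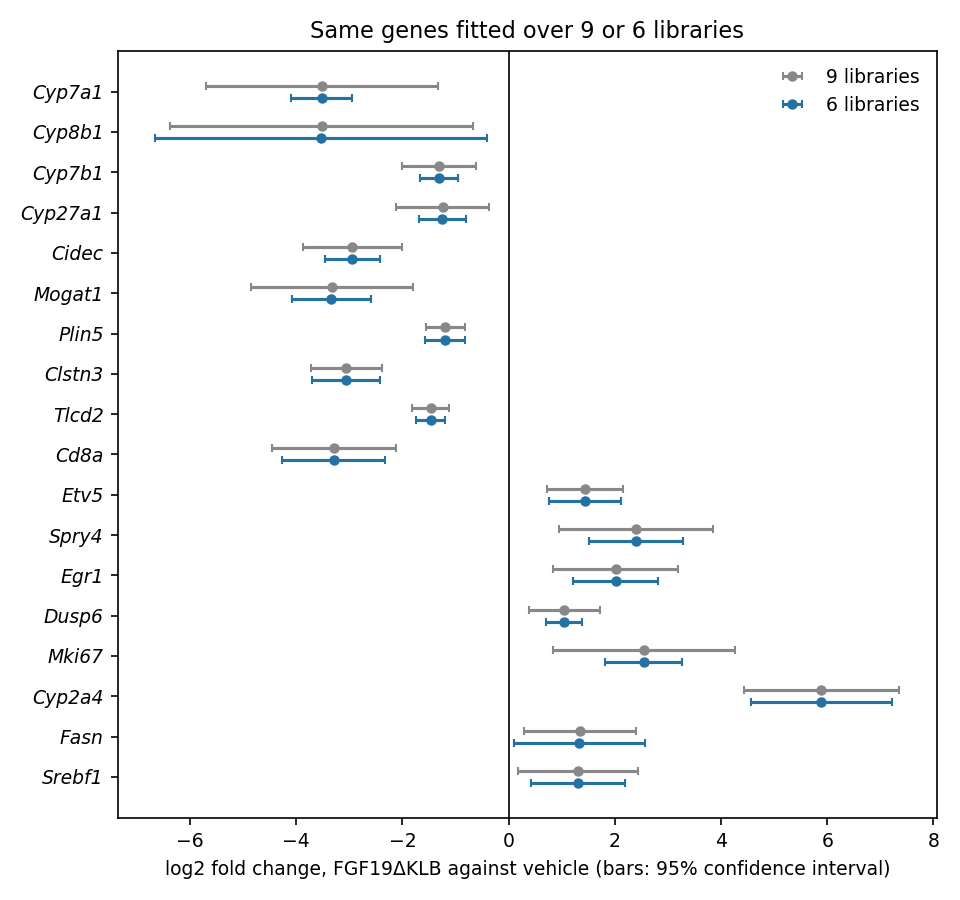
Log2 fold change of FGF19ΔKLB against vehicle (horizontal axis) with its 95% confidence interval for 18 genes, from the fit over 9 libraries and from the fit over the 6 libraries of these groups. For Cyp7a1 the interval runs from −5.70 to −1.33 over 9 libraries and from −4.10 to −2.94 over 6.

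The direct contrast of FGF19ΔKLB with FGF19WT asks where the variant differs from the natural hormone. Lipogenesis genes stood higher with FGF19ΔKLB in 21 of 22 members (median log2 change 0.96, adjusted p = 1.42e-07, adjusted p = 0.551 with an estimated correlation), with 10 rising and 1 falling adjusted over the list alone and 0 over all genes. Fasn stood at 558 ± 42.2 CPM with FGF19ΔKLB and 128 ± 26.5 with FGF19WT (SD, n = 3; log2 difference 2.13, 95% interval 1.05 to 3.20, adjusted p = 0.237). Elovl6, which lengthens fatty acids, stood at 122 ± 23.4 and 41.4 ± 21 CPM, and Pnpla5, a lipase, at 4.13 ± 1.51 and 0.145 ± 0.0904. Wnt and pericentral genes stood lower in 16 of 16 members (median −3.78, adjusted p = 4.14e-10, adjusted p = 0.551 with an estimated correlation), all 16 falling adjusted over the list alone. Periportal genes stood higher in 12 of 12 (adjusted p = 3.42e-06, adjusted p = 0.551 with an estimated correlation). These lists are the ones in which FGF19WT libraries 2 and 3 stood apart, and without both of them the Wnt and periportal lists were each at 0.441. Cyp7a1 stood at 7.52 ± 2.01 CPM with FGF19ΔKLB and 68.5 ± 58.8 with FGF19WT (log2 difference −3.19, 95% interval −5.34 to −1.03, adjusted p = 0.257). FGF19WT library 1 lay below the FGF19ΔKLB mean, so this difference came from FGF19WT libraries 2 and 3. Card10, which rose with FGF19WT, stood at 6.69 ± 0.834 CPM with FGF19ΔKLB (difference −1.54, adjusted p = 0.137), and it was chosen for this contrast after its values were seen. No gene passed in edgeR over 9 libraries, where 2267 had an unadjusted p under 0.05 and the groups did not overlap in 13.5% of genes, with chance at 10%. DESeq2 called 834 (216 higher and 618 lower with FGF19ΔKLB), limma 0 and edgeR over 6 libraries 1. The count was 1 without vehicle 1, 1 without FGF19ΔKLB 1 and 3846 without FGF19WT 1. The 1 call over 6 libraries was Adnp, which shares its strand and start with Gm20716 and moved against it, so that no change of the locus can be read from it.

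Of the 41 lists, 16 passed in the direct contrast, 12 higher and 4 lower with FGF19ΔKLB. Cell cycle genes were lower in 34 of 35 members (median −2.17, adjusted p = 1.15e-08, adjusted p = 0.551 with an estimated correlation), with 0 falling adjusted over the list alone. NRF2 targets were lower in 13 of 14 members (adjusted p = 2.82e-05, adjusted p = 0.551 with an estimated correlation), with 7 falling and 1 rising adjusted over the list alone. The glutathione transferase Gsta2 stood at 6.47 ± 1.82 CPM with FGF19ΔKLB and 65.9 ± 53.7 with FGF19WT. Acute phase genes (1.51e-06), cholesterol synthesis (1.79e-05), interferon response (7.39e-05), female-biased genes (0.000257), hepatocyte markers (0.000487), neutrophil markers (0.000625), gluconeogenesis (0.00156) and the FGF receptor complex (0.0319) were higher and transcripts of the mitochondrial genome lower (0.000289), each with adjusted p = 0.551 with an estimated correlation. Kupffer cell markers (0.000487, adjusted p = 0.604 with an estimated correlation) and B and plasma cell markers (0.0251, adjusted p = 0.612 with an estimated correlation) were higher. Kupffer cell markers lost their call without FGF19WT 3 (0.0804) and B and plasma cell markers without FGF19WT 2 (0.0703) or 3 (0.229). The FGF receptor complex lost its call without FGF19WT 2 (0.0512), FGF19WT 3 (0.0593), FGF19ΔKLB 1 (0.0587) or FGF19ΔKLB 3 (0.0682). With FGF19WT libraries 2 and 3 both left out, 9 lists passed and lipogenesis was the only one of the 16 among them. Over the 6 libraries of these groups lipogenesis was also the only list that fry passed, at 0.0132.

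**Figure D4:**
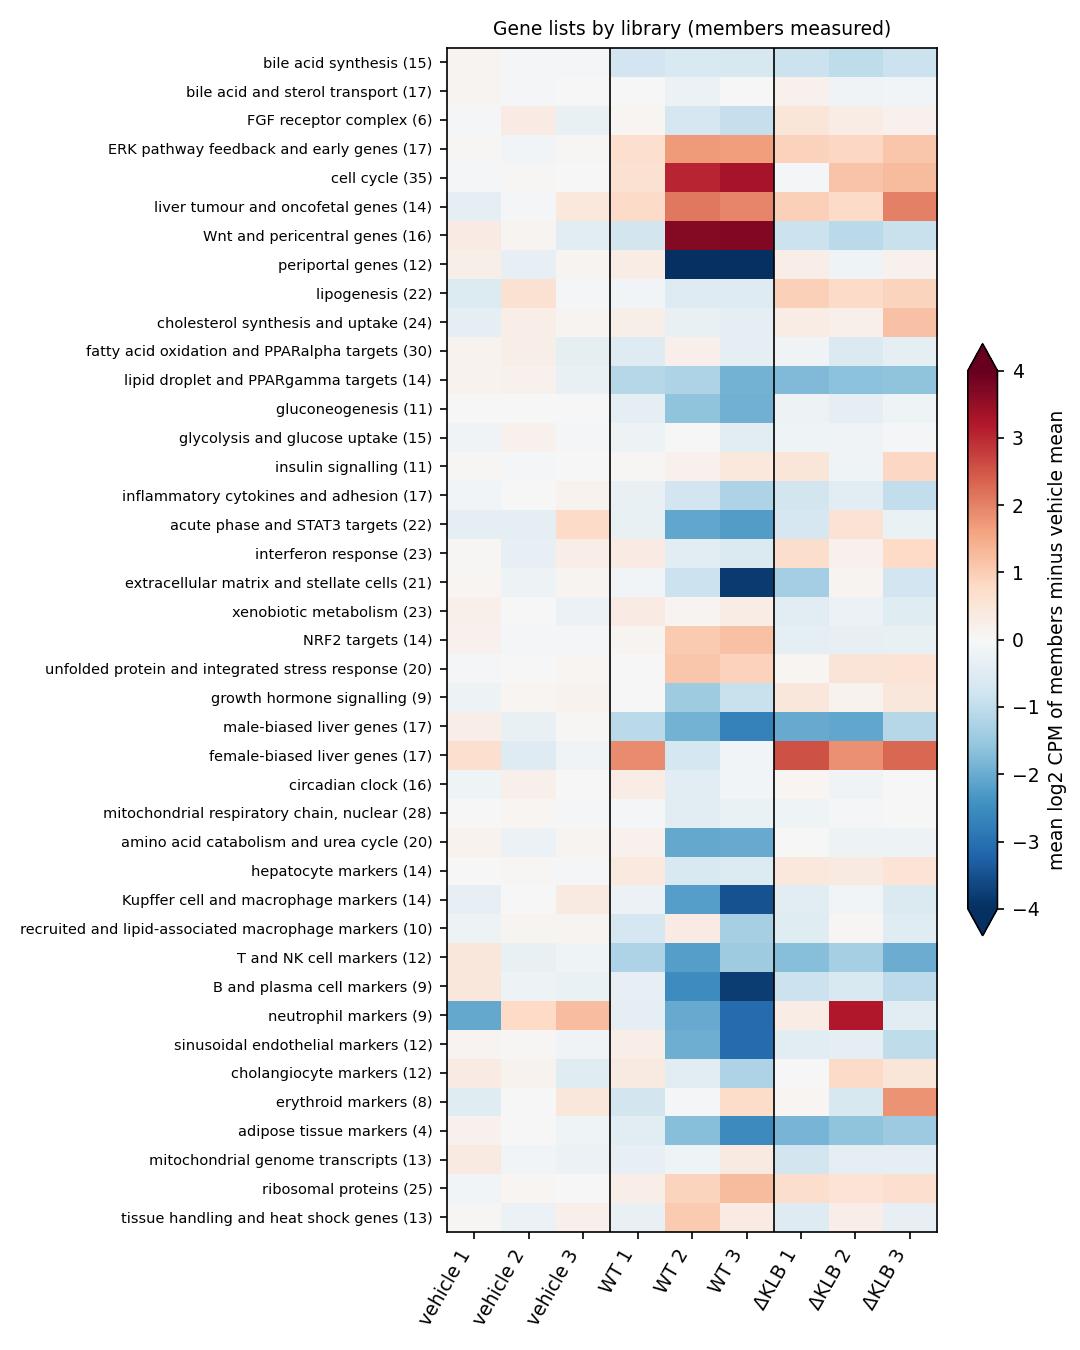
Mean log2 CPM of the members of each of 41 gene lists (vertical) in each of the 9 libraries (horizontal), as the difference from the mean of the vehicle libraries, on a colour scale in log2 units. Wnt and pericentral genes are at 3.67 and 3.69 in FGF19WT libraries 2 and 3 and at −0.75 in FGF19WT library 1, while lipid droplet genes lie between −1.9 and −1.15 in the 6 treated libraries.

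The responses to both hormones had a higher covariance than shared vehicle libraries alone gave in simulations that drew genes independently of each other. Clstn3 was the gene that passed over 9 libraries in both comparisons, where independent calls would share 0.0017. At an unadjusted p under 0.05, 463 genes were higher in both, 289 lower in both and 7 moved apart. Higher and lower in both, 99 and 48 were expected from independent calls, a figure that leaves out the shared vehicle libraries. Simulations with shared vehicle libraries gave means of 103 and 64 (maxima 122 and 81), with 1.5 moving apart (maximum 5). The simulated groups held no changes, so the numbers of genes under 0.05 were not matched to the data. In the data these were 2130 higher and 1282 lower with FGF19WT, and 841 higher and 674 lower with FGF19ΔKLB. The excess over the simulated overlaps therefore does not measure agreement alone. Across 18142 genes, which are not independent replicates, the log2 changes correlated with a Pearson r of 0.544 and a Spearman rho of 0.503. These compare with simulated means of 0.496 and 0.461 and simulated maxima of 0.52 and 0.479. The covariance was 0.676, against a simulated maximum of 0.121. Among the lists, lipid droplet genes, ERK feedback, ribosomal proteins, male-biased genes, inflammatory genes and T and NK cell markers passed in the same direction in both comparisons and kept their calls in every fit that left out 1 library. With an estimated correlation none of these 6 passed, at adjusted p = 0.593 with FGF19WT and 0.208 to 0.352 with FGF19ΔKLB. The inflammatory list stood at −0.3 from vehicle in FGF19WT library 1 and at −0.77 and −1.25 in libraries 2 and 3. Its fall with FGF19WT thus rested mostly on that pair. The shared vehicle libraries favour the same direction in both comparisons, and the agreement of lists was not simulated. Cidec (log2 difference 0.32, adjusted p = 0.75) and Cd8a (0.45, adjusted p = 0.722) did not pass between the treated groups, and both were chosen for that contrast after their values were seen. The r depended on the libraries and on the filter. Under 12 other choices of these, each set beside 7 simulations fitted the same way, r was above every simulation in 5 and below their mean in 6. It was 0.392 without FGF19ΔKLB 3 (simulated mean 0.426), 0.487 with no filter on low counts (0.493) and 0.411 without FGF19WT libraries 2 and 3 (0.329). The covariance was above every simulation under all 12.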

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

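The tests of explanations in this part were chosen after the results were seen, except for the splits of the libraries, which were planned.

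All but 1 of the results singled out here are gene lists that differed between the responses to FGF19ΔKLB and FGF19WT in the direct contrast of these groups, which was a planned test. Their camera adjusted p values were 4.14e-10 for Wnt and pericentral genes, 1.15e-08 for cell cycle genes, 1.42e-07 for lipogenesis, 1.51e-06 for acute phase genes, 3.42e-06 for periportal genes, 1.79e-05 for cholesterol synthesis, 2.82e-05 for NRF2 targets, 7.39e-05 for interferon response, 0.000257 for female-biased genes, 0.000289 for mitochondrial genome transcripts, 0.000487 for hepatocyte markers and also for Kupffer cell markers, 0.000625 for neutrophil markers, 0.00156 for gluconeogenesis, 0.0251 for B and plasma cell markers and 0.0319 for the FGF receptor complex. None of these lists passed with an estimated correlation, where the lowest adjusted p was 0.551. Fasn was singled out because the 3 FGF19ΔKLB libraries were all above the mean of vehicle and the 3 FGF19WT libraries all below it, with a log2 difference of 2.13. The difference was not tested by that comparison of directions, and in the 9-library contrast its adjusted p was 0.237. For the lists, 4 of the 10 splits of these 6 libraries passed at least as many lists as the 16 of the real split, and the highest other passed 23. The other splits that kept FGF19WT libraries 2 and 3 in 1 group passed 20, 23 and 22 lists. Those that parted this pair passed 6 to 12. The number of lists thus followed the pair, and the splits do not measure chance alone. The splits are too few for a share under 0.05.

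FGF19WT libraries 2 and 3 stand apart from FGF19WT library 1, and they carry most of these differences. FGF19WT library 1 correlated across genes with the FGF19ΔKLB libraries at 0.956, 0.958 and 0.95 and with vehicle at 0.95 to 0.953. It correlated with FGF19WT libraries 2 and 3 at 0.892 and 0.866, while the FGF19ΔKLB libraries correlated with each other at 0.953 to 0.959. Whether the label of FGF19WT library 1 is right was not tested. A swap of FGF19WT libraries 2 and 3 with vehicle libraries is argued against. The highest correlation of either with a vehicle library was 0.88 across genes, where vehicle libraries correlated with each other at 0.961 to 0.966. A larger share of pericentral tissue in the pieces taken is argued against as the whole cause. FGF19WT libraries 2 and 3 were both above the other 7 libraries in 27 of 35 cell cycle genes. Library depth or composition is argued against only as a cause shared by both, since both lay outside the other 7 on the same side in 0 of 4 measures. That test cannot speak to either library alone. FGF19WT 3 had the lowest total count (65.1 M) and the highest mitochondrial share (11.93%, next 9.84% in vehicle 1). Tumour tissue with active Wnt signalling in these pieces may explain the pattern and stays open: 5 of 14 liver tumour and oncofetal genes (Afp, Akr1c18, Ly6d, Prom1 and Scd2) were above the other 7 in both, where 2.6 would be by chance, and 4 were below; the labels record no tumours, so a response to the treatment that differed between animals cannot be told apart from it. Tissue handling or RNA quality stays open as well: 6 of 13 tissue handling and heat shock genes (Atf3, Dnajb1, Egr1, Hsp90aa1, Hspa1b and Hsph1) were above the other 7 in both, where 2.4 would be by chance (exact hypergeometric test, p = 0.021, not adjusted for the 41 lists), though Egr1 is also an ERK response gene and Atf3 a stress response gene.

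Few genes were called for FGF19ΔKLB against vehicle over 9 libraries and many over 6. The spread among the FGF19WT libraries, which enters the pooled error, may explain this. Over the 7 libraries left without FGF19WT libraries 2 and 3, 303 genes were called. The 1 FGF19WT library left adds nothing to the error, so that fit nearly repeats the 6-library fit and cannot test the explanation. The count was 172 without FGF19WT 1, which leaves FGF19WT 2 and 3, and 0 and 5 without FGF19WT 2 or FGF19WT 3. These counts go with the explanation, but those fits were not planned as a test of it. The inflated scale of the deposited counts is argued against, since dividing them by 4 gave 4 genes over 9 libraries. No biological explanation was tested for this pattern. Of the 10 splits of these 6 libraries, the real split gave 292 genes in the 6-library fit and the highest other 2, and over 9 libraries the real split gave 2 and the highest other 0. In each case 1 split gave as many, the real one. The splits are too few for a share under 0.05.

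T cell transcripts were lower in both treated groups. Dilution by a larger share of hepatocytes is argued against for FGF19ΔKLB by the cholangiocyte list alone, and only as the whole cause. The T and NK cell score was −1.73, −2.09 and −2.49 from the cholangiocyte score (mean −2.1, SD 0.38). Other lists differed. In FGF19ΔKLB 1, 2 and 3 B and plasma cell markers were at −0.85, −0.6 and −1.04 from vehicle and sinusoidal endothelial markers at −0.45, −0.35 and −1.01. Neutrophil markers were at 0.3, 3.21 and −0.44 and erythroid markers at 0.09, −0.64 and 1.79. Some dilution may add to the lower T cell transcripts, since hepatocyte markers were higher with FGF19ΔKLB (camera adjusted p = 0.00252, adjusted p = 0.515 with an estimated correlation). For FGF19WT dilution stays open, with differences of −1.58, −1.75 and −0.19 from the cholangiocyte score (mean −1.17, SD 0.86), while hepatocyte markers, at 0.38, −0.62 and −0.54 from vehicle, gave no sign of a larger hepatocyte share in libraries 2 and 3. A smaller number of T cells in the treated livers remains open for both and could not be tested without sorted cells.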

How the results depend on the processing

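The settings chosen after the data were seen were dividing counts by 4, leaving out FGF19WT libraries 2 and 3 with either filter, and all alternatives of the 6-library fit. No named gene reversed a call in the settings run. Of 2033 values of named genes under the alternatives for FGF19WT against vehicle, 130 lost and 142 gained a call. Of 2085 for FGF19ΔKLB against vehicle, 15 lost and 222 gained one. Of 1497 for FGF19ΔKLB against FGF19WT, 107 gained one. A further 193, 48 and 171 were called on neither side and moved by at least 1 SE. Leaving out FGF19WT libraries 2 and 3 moved 76 of 109 values in the first comparison and 62 of 80 in the last. Against counts of 20 genes for FGF19WT against vehicle, 2 for FGF19ΔKLB against vehicle, 0 for FGF19ΔKLB against FGF19WT and 292 for the 6-library fit of FGF19ΔKLB, the DESeq2 test gave 1743, 370, 834 and 1378, and limma gave 69, 51, 0 and 469. The 6 libraries of each pair gave 1, 292 and 1. For FGF19ΔKLB against vehicle no filter gave 11, the stricter filter 13 and counts divided by 4 gave 4. Without FGF19WT libraries 2 and 3 there were 20 for FGF19WT against vehicle (11 rose, 9 fell), of which 3 were among the 20 over 9 libraries, and 303 for FGF19ΔKLB against vehicle (290 with the genes tested over 9 libraries) and 7 for FGF19ΔKLB against FGF19WT, and 9 lists in place of 16 in the latter. Leaving out each library in turn gave 0–5221, 0–172, 0–3846 and 44–276 genes, and the similarity of the responses ranged over 0.392–0.56 around 0.544, at 0.487 with no filter and 0.411 without FGF19WT libraries 2 and 3 (0.421 with the genes tested over 9 libraries). Of 21, 22 and 16 lists, 14, 14 and 13 kept their call in every fit without 1 library, and 7, 22 and 1 without FGF19WT libraries 2 and 3, where the Wnt list turned for FGF19WT. The cause was not tested for the tools, and fits with fewer libraries also have fewer degrees of freedom. In some of these fits the filter also let in other members of a list. Without FGF19WT libraries 2 and 3 the adipose list had 9 members in place of 4, and with these it turned for FGF19WT as well. For FGF19ΔKLB against vehicle the fit without FGF19WT libraries 2 and 3 nearly repeats the 6-library fit, so lists kept there are little further evidence.

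With the replicate number as a block, 1 gene was called for FGF19WT against vehicle, 0 for FGF19ΔKLB against vehicle and 103 in the 6-library fit, of which 84 were among the 292. The block takes degrees of freedom. Deviations of equally numbered libraries from their group means correlated across genes at −0.048 to 0.147, against −0.178 to 0.138 for unequal numbers. For FGF19ΔKLB against vehicle equal numbers gave 0.064, 0.03 and 0.038, above the −0.057 to 0.015 of unequal numbers. For FGF19WT against vehicle they gave −0.023, −0.021 and −0.028, below the 0.007 to 0.02 of unequal numbers. These small values point in opposite directions and do not settle whether the numbers pair the libraries.

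Alternatives for FPKM alone (quantile normalization, median ratios, other pseudocounts and limma without robust and trend) were not run, since the table holds counts. At 16.3 to 18.3 M read pairs per library, genes with no counts in a group have only a bound on their fold, and in simulated data most 2-fold changes were missed over 9 libraries, with 3% recovered for FGF19WT against vehicle and 4.5% for FGF19ΔKLB.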

Other observations

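In this part the list test and the splits of the libraries were planned, and Cux2, Bcl6, Ghr, Stat5a, Gsta2, Abcg5, Gm20716, Cela1, Ctrb1 and Amy2a5 were chosen after their values were seen.

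The list of growth hormone signalling genes did not pass with FGF19ΔKLB (adjusted p = 0.851 over 9 libraries and 0.908 over 6). Of its 9 members 1 rose (Cux2) and 3 fell (Bcl6, Ghr and Stat5a) over all genes in the 6-library fit. The female-biased repressor Cux2 rose from 4.66 ± 2.26 to 44.1 ± 12.1 CPM (log2 fold change 3.24, SE 0.39, adjusted p = 0.0218) and the male-biased repressor Bcl6 fell from 22.4 ± 5.77 to 5.47 ± 2.02 CPM (−2.03, SE 0.33, adjusted p = 0.0396). Leaving out 1 of the 6 libraries kept the call of Cux2 in 2 of 6 fits and that of Bcl6 in 0. Ghr, the growth hormone receptor, changed by −0.79 (adjusted p = 0.0391, called in 1 of 6 such fits) and Stat5a by −0.71 (adjusted p = 0.048, called in 0). Cyp4a12a, a male-biased fatty acid hydroxylase, fell from 185 ± 116 to 0.846 ± 0.566 CPM (adjusted p = 0.0219), a call made in 1 of 6 such fits. With FGF19WT, Cux2 stood at 17.9, 0.148 and 8.95 CPM and Bcl6 at 13.6, 14.5 and 9.74 CPM (adjusted p = 0.645 and 0.216 over 9 libraries). Gsta2, a glutathione transferase, fell from 79.9 ± 30.1 to 6.47 ± 1.82 CPM with FGF19ΔKLB (−3.63, SE 0.33, adjusted p = 0.0111), and Abcg5, which exports sterols into bile, rose from 56.5 ± 7.97 to 129 ± 15.2 CPM (1.19, SE 0.15, adjusted p = 0.0187). Gsta2 was called in all 6 fits that leave out 1 library and Abcg5 in 3.

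On chromosome 2 from 168180986, Adnp and Gm20716 start at the same base of the same strand. Adnp stood near 0 in vehicle library 1 (0.0668 CPM) and the 3 FGF19WT libraries (0.0586, 0.247 and 0.203) and between 45 and 52.8 CPM in the other 5. Gm20716 stood at 65.6 CPM in vehicle library 1, at 3.84, 62.8 and 68.9 in FGF19WT and at 0 in the other 5. Of 11 listed pancreas genes 7 are in the table, and Cela1, an elastase, was the only one past the low-count filter over 9 libraries. Cela1 stood at 7.44, 7.51 and 6.69 CPM in vehicle, at 12.4, 55.6 and 55 with FGF19WT and at 9.64, 11.2 and 14.2 with FGF19ΔKLB. Ctrb1 stood at 6.49 CPM in FGF19WT library 1 and at 0 in the other 8, and Amy2a5 at 1.46 and 2.42 CPM in FGF19WT libraries 2 and 3 and at 0 in the other 7.

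The planned splits of the libraries gave the following for the other counts. For FGF19WT against vehicle the real split gave 20 genes and the highest other 1, with 1 split giving as many, and 21 lists against 23, with 3 splits giving as many. The other splits of that comparison that kept FGF19WT libraries 2 and 3 in 1 group passed 22, 19 and 23 lists. Those that parted this pair passed 4 to 10, so the number of lists followed the pair. For FGF19ΔKLB against vehicle the real split passed 22 lists and the highest other 12, with 1 split giving as many. For FGF19ΔKLB against FGF19WT the real split gave 0 genes and the highest other 2, so all 10 splits gave as many. With 10 splits each, they are too few for a share under 0.05.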
